A study of Saccharomyces cerevisiae with 34 samples.

How the data were processed

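RNA from Saccharomyces cerevisiae Sigma1278b strains was measured by sequencing of polyadenylated transcripts. The strains carry different numbers of glutamine-rich tandem repeats (the region called TR2 in the labels) in SSN6, whose gene symbol in the files is CYC8. Its protein acts with Tup1 as a general transcriptional corepressor. The labels list 34 libraries in 17 groups of 2: variants with 0, 14, 27, 33, 55, 90 and 105 repeats and a wild type with 63 repeats at 4% glucose, and the same with a further variant of 20 repeats at 0% glucose. Cells grew at 4% glucose, part of each culture was harvested, and the rest was harvested 2 hours after transfer to medium lacking glucose, so each strain's samples in the media come from shared cultures.

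Per the submitters' processing notes, the tools were TopHat2 2.0.7 and edgeR, whose version is not given. The genome build, the annotation, the counting step and the test used are not given in the sources used here. No file holds values per library. The authors deposited 15 comparison tables, 7 at 4% glucose and 8 at 0% glucose, each with 7126 rows. The deposited values are log2 fold changes and log2 mean CPM (counts scaled to the library total) on the log2 scale, together with a p-value per gene and a p-value adjusted by the method of Benjamini and Hochberg over all rows. The direction was checked on the values: when the group levels were rebuilt from each table, the level of the denominator group varied between tables of a medium with an SD of 0.00244 to 0.0296, against 0.0608 to 0.178 for the numerator group. The fold changes are therefore variant over wild type. Median log2 fold changes of the tables lay between -0.02 and 0.01.

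Depth was read from the lowest deposited mean levels, which lie on steps of whole reads: between 94.6% and 100% of the low values were whole multiples within a tolerance of 0.1. It came to between 35.7 and 59.6 M reads (M, mega) per comparison of 4 libraries at 4% glucose and between 46.0 and 136 M at 0% glucose. The depth of a single library is unknown, and so is the spread between replicates of a group. Row names were matched to the annotation of assembly R64, used for names and gene order alone: 6161 rows matched a symbol or locus name, 6201 with synonyms, and 925 did not match. The copy of the reference may differ from the build the authors used. Rows of the mitochondrial genome hold no reads in any table. FLO11 is listed as MUC1, GPP1 as RHR2 and GPP2 as HOR2.

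The tests and 34 gene lists were fixed before the data were examined. The design foresaw tests on counts, to be replaced by tests on the comparison tables if the deposit held no counts, and the latter were run. A gene was called at a deposited adjusted p under 0.05. Lists with at least 5 measured members were tested with limma 3.58.1 (cameraPR, R 4.3.3) on signed z values from the deposited p, at a preset inter-gene correlation of 0.01, adjusted over all lists and comparisons of a medium. An alternative estimated the correlation of each list across the variants of the medium. That estimate includes any response the members share between variants, so its p is the stricter one. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

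The trend with repeat number was Spearman's rho of a gene's log2 fold change over the variants of a medium, with an exact two-sided permutation p, and with 100 random reassignments of repeat numbers to variants (seed 1). Differences between media, and between 105 and 0 repeats, used z values. As the tables give no standard error, one was rebuilt for each gene and medium as the median over its comparisons with p under 0.9 of the absolute log2 fold change divided by the normal quantile of p. Differences between media used this median. For 105 minus 0 repeats, and for other differences between variants, the value from each comparison's own p was used instead. The median only filled gaps there. A value from a single p is less steady than the median. For 105 minus 0 repeats, the part of the variance owed to the shared wild type libraries was taken off. These z tests are approximate. Tested on simulated data with 6913 genes, of which 200 were changed by 1 on the log2 scale, they recovered 82.5% of changed genes between media and 86.0% and 91.5% between 105 and 0 repeats. The trend at p under 0.05 recovered 89.5% and 92.5%, but 63.8% and 65.5% of its calls were unchanged genes. The simulation drew normal errors of the rebuilt size, independent between media, with equal variance for variant and wild type. The z tests assume the same, so their recovery on the deposited values is not shown. Overlap between variants was compared with independent calls and with simulated unchanged groups against shared wild type libraries.

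Named genes followed a fixed rule. CYC8 and TUP1 are always given. For 0 and 105 repeats, the 10 largest rises and falls among called genes with log2 CPM of at least 2 are given, and for other variants the 3 largest of each. Trends and differences have the 5 most extreme genes of each direction, and lists up to 4 called members. Alternatives covered the threshold (adjusted p under 0.01, or at least 2-fold), low levels (log2 CPM of at least 2), genes present in every table, centring on each table's median, the list statistic, the trend statistic and left-out variants, and the standard errors. After the data were seen, alternatives without 16 rows of the ribosomal DNA locus and without the 90 and 105 repeat variants were added. Alternatives that need counts per library could not be run.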

Results

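The transcriptomes of budding yeast with different numbers of SSN6 tandem repeats were compared with wild type, which carries 63 repeats, in glucose-rich medium (4% glucose) and 2 hours after transfer to medium without glucose (0% glucose). Each of the 17 groups has 2 libraries, and the deposit holds 15 variant-over-wild-type comparisons, not values per library. The 4 libraries of a comparison together held 35.7 to 59.6 M reads (M, mega) at 4% glucose and 46.0 to 136 M reads at 0% glucose. A gene is said to have risen or fallen where the deposited adjusted p lay under 0.05. A gene list is said to have done so where its limma test passed that threshold. Counts of list members are over all measured members. Medians of a list are over members with a mean log2 CPM of at least 2 in the medium, or in both comparisons for a difference. All fold changes are variant over wild type on the log2 scale.

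Wild type levels give the background. Rebuilt from the tables, HSP12 stood at 8.14 CPM (counts scaled to the library total) in wild type at 4% glucose and at 269 without glucose, CTT1 at 19.9 and 73.4, and PCK1 at 11.8 and 245. The media were normalized apart, so these levels across media are approximate.

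The transcript that carries the repeats was itself compared first. In the authors' deposited table of each of the 7 variants at 4% glucose, CYC8 had a log2 fold change between -0.09 (105 repeats) and 0.28 (33 repeats), and none was called, with adjusted p of at least 0.996. At 0% glucose CYC8 rose by 0.49 with 0 repeats (adjusted p = 0.00373), 0.39 with 14 repeats (0.000353) and 0.44 with 33 repeats (0.0187), and fell by 0.28 with 90 repeats (0.0229), in the authors' deposited table. TUP1, the partner subunit, ranged from -0.21 to 0.07 over both media in the authors' deposited table and was called in none.

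**Figure D1:**
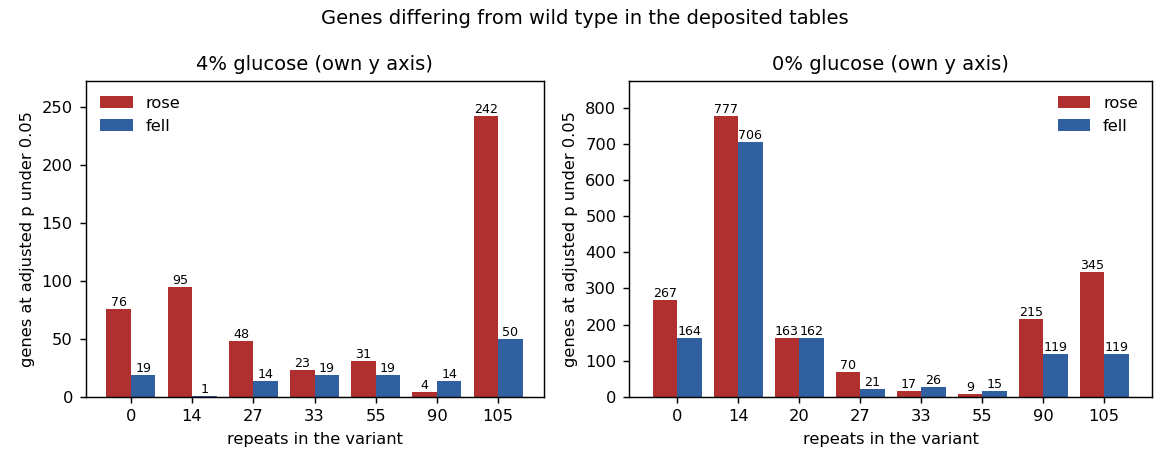
Number of genes that rose or fell against wild type at a deposited adjusted p under 0.05 (y axis, own scale per panel) for each number of repeats (x axis), at 4% glucose on the left and at 0% glucose on the right. The totals of both directions are highest with 105 repeats at 4% glucose (242 rose, 50 fell) and with 14 repeats at 0% glucose (777 rose, 706 fell), and lowest with 90 repeats at 4% glucose (4 rose, 14 fell) and 55 repeats at 0% glucose (9 rose, 15 fell). Falls alone are fewest at 4% glucose with 14 repeats (1 fell). These numbers also depend on the standard errors, which differ between comparisons.

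Comparisons at 4% glucose asked which transcripts differ from wild type when glucose is plentiful. With 0 repeats, the authors' deposited table gave rises of 2.74 for HSP12, a small membrane-associated heat shock protein, 2.03 for DDR2, 1.62 and 1.44 for the small heat shock chaperones HSP26 and HSP42, and 1.08 for CTT1, the cytosolic catalase. YNR034W-A (1.42), RTC3 (1.23), the hydrophilin GRE1 (1.15), BSC1 (1.14) and PRM7 (1.07) complete the 10 largest rises in the authors' deposited table, with adjusted p from 8.63e-70 for HSP12 to 0.000119 for GRE1. All of the 10 largest falls in the authors' deposited table were rows of the ribosomal DNA locus, from -1.77 for RDN18-2 (adjusted p = 3.86e-35) through RDN18-1 (-1.76), YLR154W-F (-1.72), RRT15 (-1.64), RDN37-2 (-1.51), RDN37-1 (-1.51), YLR154W-B (-1.48), YLR154C-G (-1.45) and RDN25-2 (-1.43) to TAR1 (-1.43). In all, 95 genes were called, of which 76 rose and 19 fell. A total of 80 remained with the rows of that locus left out.
Among 36 general stress genes with 0 repeats at 4% glucose, 17 rose and 0 fell, 20 when adjusted over the list alone (median 0.35, adjusted p = 5.23e-63; adjusted p = 0.00107 with an estimated correlation). The osmotic stress list of Sko1 type rose too, with 7 of 14 members up and 8 adjusted over the list alone (median 0.43, adjusted p = 5.63e-19; adjusted p = 0.0113 with an estimated correlation). Leading members were RTC3 (1.23), HOR7 (0.78), HOR2 (0.66), a glycerol phosphatase, and ENA5 (0.59) in the authors' deposited table. Hexose transporters rose, 4 of 19 with 4 adjusted over the list alone (median 0.29, adjusted p = 1.74e-05; adjusted p = 0.0191 with an estimated correlation), and were HXT5 (0.76), HXT6 (0.55), HXT7 (0.51) and HXT2 (0.45) in the authors' deposited table. The list of abundant RNA without poly(A) tails, a sign of RNA quality, fell beside these, with 8 of 22 members down and 8 adjusted over the list alone (median -0.74, adjusted p = 6.28e-50; adjusted p = 0.000235 with an estimated correlation). The RNA quality list holds rows of the ribosomal DNA locus, among them copies and overlapping rows of the same transcript. Its members are therefore not independent, and the list and the median of the ribosomal DNA rows are not separate signs. A further 9 lists passed with the preset correlation, with adjusted p between 0.208 and 0.933 with an estimated correlation.

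With 14 repeats at 4% glucose, 95 genes rose and 1 fell. HSP12 rose by 3.50 (adjusted p = 2.52e-94), HXK1, the glucose-repressed hexokinase, by 2.05 (1.61e-43) and HSP42 by 2.04 (9.81e-36) in the authors' deposited table. FIT2, a cell wall protein of iron uptake, fell by 0.88 (1.33e-06) in the authors' deposited table. General stress genes rose, 23 of 36 with 29 adjusted over the list alone (median 0.67, adjusted p = 1.33e-134; adjusted p = 1.25e-07 with an estimated correlation), led by HSP12, SIP18 (2.13), DDR2 (2.03) and HSP26 (2.00) in the authors' deposited table. Hexose transporters rose, 4 of 19 with 7 adjusted over the list alone (median 0.33, adjusted p = 6.14e-07; adjusted p = 0.00436 with an estimated correlation). The high-affinity carriers HXT6 and HXT7 both rose by 1.07 in the authors' deposited table. Heat shock chaperones rose, 6 of 24 with 6 adjusted over the list alone (median 0.13, adjusted p = 1.22e-17; adjusted p = 0.0334 with an estimated correlation). The Sko1-type list rose, 6 of 14 with 8 adjusted over the list alone (median 0.45, adjusted p = 1.49e-23; adjusted p = 0.00335 with an estimated correlation). Flocculins rose, 2 of 9 with 3 adjusted over the list alone (median 0.29, adjusted p = 2.80e-08; adjusted p = 0.0334 with an estimated correlation), through FLO10 (0.92) and MUC1, the flocculin FLO11 (0.92), in the authors' deposited table. The median of the ribosomal DNA rows was -0.31 here.

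With 27 repeats at 4% glucose, HSP12 rose by 3.33 (adjusted p = 8.51e-79), BSC1 by 1.80 (5.48e-14) and HSP42 by 1.75 (1.89e-21) in the authors' deposited table. Of 62 called genes 48 rose and 14 fell, the largest falls being RDN18-1 (-1.65), RDN18-2 (-1.64) and YLR154W-F (-1.54) in the authors' deposited table. The general stress list rose, 14 of 36 with 24 adjusted over the list alone (median 0.46, adjusted p = 3.00e-77; adjusted p = 0.000235 with an estimated correlation), as did the Sko1-type list, 5 of 14 with 7 adjusted over the list alone (median 0.36, adjusted p = 2.88e-15; adjusted p = 0.0316 with an estimated correlation). Hexose transporters rose, 3 of 19 with 5 adjusted over the list alone (median 0.32, adjusted p = 2.97e-05; adjusted p = 0.0236 with an estimated correlation), and flocculins, 2 of 9 with 2 adjusted over the list alone (median 0.26, adjusted p = 4.03e-11; adjusted p = 0.01 with an estimated correlation). Ribosomal DNA rows had a median of -1.27.

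With 33 repeats at 4% glucose, 23 genes rose and 19 fell. HSP12 rose by 2.21 (adjusted p = 1.94e-45), HXK1 by 1.24 (2.68e-23) and BSC1 by 1.06 (0.000501) in the authors' deposited table. In the authors' deposited table RDN18-1 fell by 1.71, RDN18-2 by 1.70 and COS10, a subtelomeric gene, by 1.53 (adjusted p = 1.21e-10). Among general stress genes, 8 of 36 rose with 10 adjusted over the list alone (median 0.16, adjusted p = 4.47e-32; adjusted p = 0.0334 with an estimated correlation), among them CTT1 (0.87) and the glycogen phosphorylase GPH1 (0.86) in the authors' deposited table. Here the ribosomal DNA rows had a median of -1.21, and 30 calls remained without these rows.

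With 55 repeats at 4% glucose, 31 genes rose and 19 fell. HSP12 rose by 2.42 (adjusted p = 5.51e-57), VPS71, a subunit of the SWR1 chromatin remodeller, by 0.98 (4.36e-12) and HSP42 by 0.95 (1.21e-09), and RDN18-2 and RDN18-1 fell by 1.60 and COS10 by 1.57 (8.70e-14) in the authors' deposited table. Of the general stress list, 10 of 36 rose with 17 adjusted over the list alone (median 0.23, adjusted p = 4.51e-41; adjusted p = 0.0129 with an estimated correlation), and heat shock chaperones, 4 of 24 with 6 adjusted over the list alone (median 0.14, adjusted p = 1.00e-16; adjusted p = 0.0397 with an estimated correlation). Iron uptake genes fell, 3 of 23 with 5 adjusted over the list alone (median -0.15, adjusted p = 1.07e-09; adjusted p = 0.253 with an estimated correlation), namely FIT2 (-0.52), FRE2 (-0.49) and ARN2 (-0.44) in the authors' deposited table. For the ribosomal DNA rows the median was -1.08.

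With 90 repeats at 4% glucose, 4 genes rose and 14 fell, and 6 calls remained without the ribosomal DNA rows. HSP12 rose by 1.88 (adjusted p = 4.04e-32), COS12 by 1.04 (1.72e-08) and HXK1 by 0.53 (0.00116), and RDN18-2 fell by 1.76, RDN18-1 by 1.75 and YLR154W-F by 1.65 (1.88e-29) in the authors' deposited table. General stress genes rose as a list, 1 of 36 members being called and 6 adjusted over the list alone (median 0.09, adjusted p = 1.30e-12; adjusted p = 0.390 with an estimated correlation). The RNA quality list fell, 6 of 22 with 7 down and 1 up adjusted over the list alone (median -0.30, adjusted p = 1.39e-56; adjusted p = 0.000102 with an estimated correlation).

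With 105 repeats at 4% glucose, a different set led the rises in the authors' deposited table: YMR316C-B (1.87), the membrane protein YRO2 (1.82), ECM12 (1.74), SPS4 (1.72), HBN1 (1.64), YMR317W (1.63), SNZ1 of vitamin B6 synthesis (1.61), YHR022C (1.52), YOL150C (1.42) and DDR48 (1.41, adjusted p = 4.73e-29). Falls in the authors' deposited table were led by YER135C (-1.46), COS10 (-1.26), MFA1, a precursor of the mating pheromone a-factor (-1.04), the polygalacturonase PGU1 (-0.93), RIB4 of riboflavin synthesis (-0.90), FUS1 of cell fusion (-0.81), BAR1, the protease that degrades alpha-factor (-0.81), URA1 (-0.76), TIR3 (-0.71) and RDN18-1 (-0.71, adjusted p = 0.0251). Of 292 called genes, 242 rose and 50 fell. The a-specific genes fell, 4 of 7 with 6 adjusted over the list alone (median -0.48, adjusted p = 3.89e-14; adjusted p = 0.00172 with an estimated correlation), AGA2 by 0.67 and MFA2 by 0.48 beside MFA1 and BAR1 in the authors' deposited table. The pheromone pathway list fell, 3 of 21 with 3 down and 1 up adjusted over the list alone (median -0.09, adjusted p = 0.00659; adjusted p = 0.0334 with an estimated correlation), namely FUS1, SST2 (-0.53) and AGA1 (-0.52) in the authors' deposited table.
The Sko1-type osmotic list rose with 105 repeats at 4% glucose, 8 of 14 with 9 adjusted over the list alone (median 0.45, adjusted p = 2.90e-23; adjusted p = 0.00337 with an estimated correlation), led by GRE2 (1.28), the sodium pump gene ENA2 (0.82) and the glycerol phosphate dehydrogenase GPD1 (0.80) in the authors' deposited table. Hypoxic genes rose, 7 of 21 against 1 down, 8 and 2 adjusted over the list alone (median 0.23, adjusted p = 5.81e-05; adjusted p = 0.0495 with an estimated correlation). Among them ROX1 (0.70), CYC7 (0.65) and SCM4 (0.54) were up and the sterol transporter PDR11 (-0.51) down in the authors' deposited table. A rise was seen in general stress genes, 11 of 36 with 19 adjusted over the list alone (median 0.29, adjusted p = 4.80e-16; adjusted p = 0.271 with an estimated correlation). Genes of nitrogen catabolite repression rose, 6 of 26 with 6 adjusted over the list alone (median 0.19, adjusted p = 9.97e-08; adjusted p = 0.287 with an estimated correlation), among them the amino acid permease GAP1 (1.13) and the transaminase CAR2 (0.89) in the authors' deposited table. Gluconeogenic genes rose, 8 of 27 against 1 down, 12 and 1 adjusted over the list alone (median 0.27, adjusted p = 2.61e-06; adjusted p = 0.185 with an estimated correlation), including the activator ADR1 (1.05) in the authors' deposited table. The median of the ribosomal DNA rows was -0.65.

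**Figure D2:**
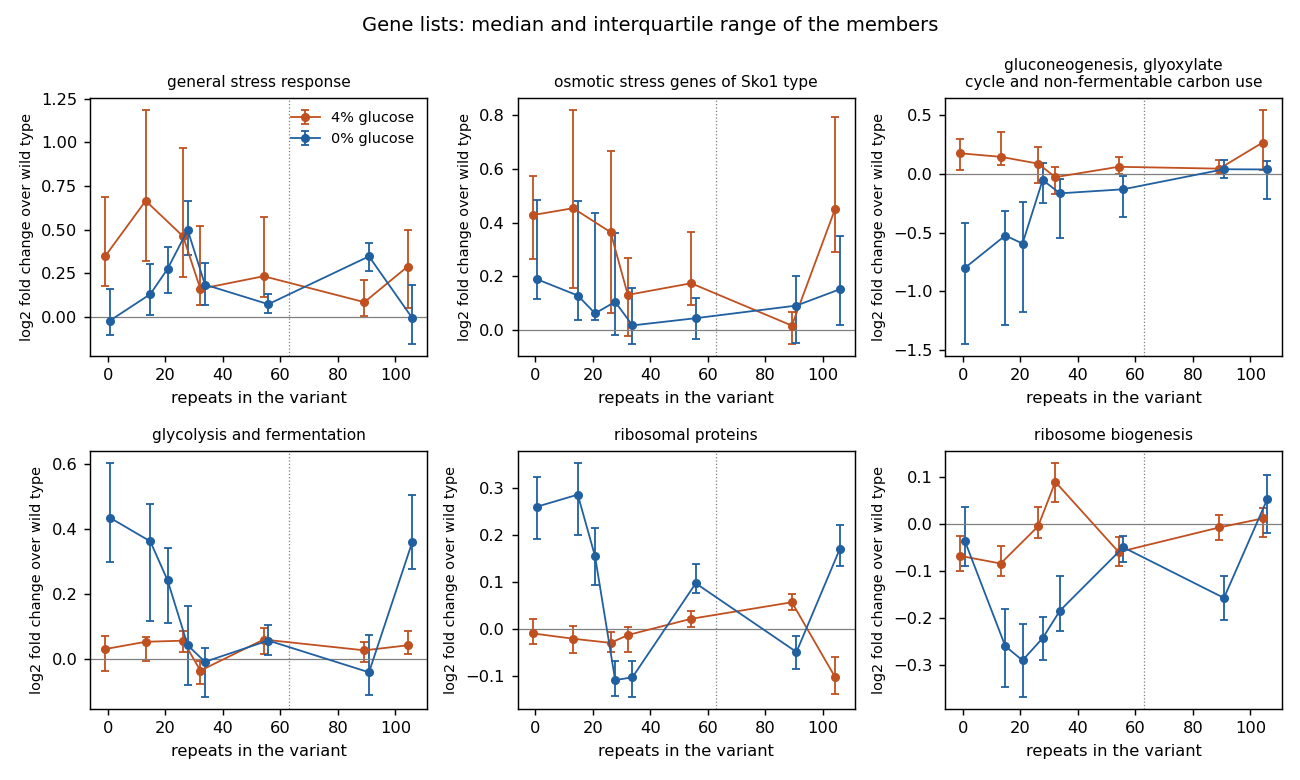
Median log2 fold change over wild type of the members of 6 gene lists with a mean log2 CPM of at least 2 in the medium (points) and their interquartile range (bars) against the number of repeats, at 4% and at 0% glucose, with wild type's 63 repeats as a dotted line and the media shifted sideways. The general stress list has its highest median, 0.67, with 14 repeats at 4% glucose, and the gluconeogenic list its lowest, -0.80, with 0 repeats at 0% glucose.

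Comparisons at 0% glucose asked how the variants differ from wild type after glucose removal. With 0 repeats, genes of the glyoxylate cycle and gluconeogenesis fell in the authors' deposited table: MLS1, malate synthase (-2.56, adjusted p = 2.49e-48), PCK1, the gluconeogenic carboxykinase (-2.40, 2.05e-67), the acetate carrier ADY2 (-2.31), the succinate-fumarate carrier SFC1 (-2.19), ICL1, isocitrate lyase (-2.04), IDP2 (-1.60) and the carnitine acetyltransferase YAT2 (-1.54). IZH4 (-1.89), the glutamate dehydrogenase GDH2 (-1.56) and ECM13 (-1.47) complete the 10 largest falls in the authors' deposited table. The largest rises in the authors' deposited table were HSP26 (1.56), the cell wall gene TIR3 (1.36), the isomaltase IMA1 (1.35), YJR115W (1.18), the S phase cyclin CLB6 (1.16), the regulator CIN5 (1.10), the metallothionein genes CUP1-2 (1.08) and CUP1-1 (1.03), YHR054W-A (1.05) and YNR014W (1.05, adjusted p = 7.07e-11). In all 267 genes rose and 164 fell.
Gluconeogenic genes fell with 0 repeats at 0% glucose, 21 of 27 and none up, with 23 down and 1 up adjusted over the list alone (median -0.80, adjusted p = 5.56e-83; adjusted p = 7.44e-05 with an estimated correlation). Genes of beta-oxidation fell, 10 of 21 with 10 adjusted over the list alone (median -0.35, adjusted p = 6.79e-15; adjusted p = 0.263 with an estimated correlation), led by FOX2 (-1.16) and ECI1 (-0.80) in the authors' deposited table. Glycolytic genes rose, 14 of 23 with 17 up and 1 down adjusted over the list alone (median 0.44, adjusted p = 3.31e-16; adjusted p = 0.109 with an estimated correlation), led by pyruvate kinase CDC19 (0.97), GPM1 (0.94) and enolase ENO2 (0.89) in the authors' deposited table. Ribosomal protein genes rose, 16 of 138 with 44 adjusted over the list alone (median 0.26, adjusted p = 2.04e-20; adjusted p = 0.530 with an estimated correlation). Corepressor partners rose, 7 of 16 with 11 up and 1 down adjusted over the list alone (median 0.36, adjusted p = 1.03e-08; adjusted p = 0.0797 with an estimated correlation), the repressors NRG1 (1.03) and NRG2 (0.66), PHD1 (0.99) and SUT1 (0.86) being largest in the authors' deposited table. The ribosomal DNA rows had a median of -0.54 beside these lists.

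With 14 repeats at 0% glucose, 777 genes rose and 706 fell. PCK1 fell by 2.29 (adjusted p = 9.43e-114) and ADY2 and MLS1 by 2.04, while CLB6 rose by 1.42 (3.64e-23), IMA1 by 1.3 and CIN5 by 1.15 in the authors' deposited table. Gluconeogenic genes fell, 22 of 27 with 23 adjusted over the list alone (median -0.53, adjusted p = 6.00e-55; adjusted p = 0.00191 with an estimated correlation). Ribosomal protein genes rose, 95 of 138 with 109 adjusted over the list alone (median 0.28, adjusted p = 6.44e-26; adjusted p = 0.457 with an estimated correlation), and ribosome biogenesis genes fell, 51 of 87 with 70 down and 1 up adjusted over the list alone (median -0.26, adjusted p = 1.04e-19; adjusted p = 0.457 with an estimated correlation). The largest of these were RPS28B (0.65) and RPS29A (0.63) against the helicase DBP2 (-1.37) and NOG2 (-0.61) in the authors' deposited table. Most of the calls were small changes: 45 genes differed by at least 2-fold, against 46 with 0 repeats. The median rebuilt standard error, over genes with log2 CPM over 5, was 0.096 here and 0.130 with 0 repeats. Numbers of calls therefore do not rank the variants by size of effect. Ribosomal DNA rows had a median of -0.15.

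With 20 repeats, measured at 0% glucose alone, PCK1 fell by 2.13 (adjusted p = 9.20e-56), MLS1 by 2.07 (4.90e-28) and ICL1 by 1.93 (2.33e-48) in the authors' deposited table. The largest rises in the authors' deposited table were RDN18-1 (1.39, adjusted p = 2.88e-22), RDN18-2 (1.36) and YLR154W-F (1.34), and the ribosomal DNA rows had a median of 1.08, opposite in sign to those with 0 and 14 repeats. Of 325 called genes, 163 rose and 162 fell. Gluconeogenic genes fell, 15 of 27 with 20 down and 1 up adjusted over the list alone (median -0.59, adjusted p = 1.81e-54; adjusted p = 0.00191 with an estimated correlation). Ribosome biogenesis genes fell, 15 of 87 with 49 adjusted over the list alone (median -0.29, adjusted p = 1.10e-23; adjusted p = 0.419 with an estimated correlation), and general stress genes rose, 11 of 36 with 18 adjusted over the list alone (median 0.28, adjusted p = 5.40e-12; adjusted p = 0.332 with an estimated correlation).

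With 27 repeats at 0% glucose, YJR115W rose by 1.40 (adjusted p = 5.11e-12), YNR014W by 1.08 and IMA1 by 1.02, and COS10 fell by 1.34 (1.27e-08), MLS1 by 1.27 (1.86e-14) and the weak-acid pump PDR12 by 1.12 in the authors' deposited table. Of 91 called genes, 70 rose and 21 fell. Members of the general stress list rose, 17 of 36 with 27 adjusted over the list alone (median 0.50, adjusted p = 4.14e-53; adjusted p = 0.000639 with an estimated correlation), led by CTT1 (0.98), RTN2 (0.94), SOL4 (0.87) and HSP12 (0.81) in the authors' deposited table. Gluconeogenic genes fell, 5 of 27 with 7 down and 1 up adjusted over the list alone (median -0.05, adjusted p = 3.40e-05; adjusted p = 0.625 with an estimated correlation). Here the ribosomal DNA rows had a median of 0.26.

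With 33 repeats at 0% glucose, 17 genes rose and 26 fell. IMA1 rose by 0.87 (adjusted p = 5.91e-07), PGU1 by 0.85 (0.000116) and TIR3 by 0.71 (0.00999) in the authors' deposited table. COS10 fell by 1.47 (adjusted p = 0.00310), RDN18-2 by 1.14 and RDN18-1 by 1.10 in the authors' deposited table. Gluconeogenic genes fell, 6 of 27 with 8 adjusted over the list alone (median -0.17, adjusted p = 5.74e-11; adjusted p = 0.419 with an estimated correlation), among them MLS1 (-1.09), SFC1 (-0.82), ICL1 (-0.73) and ADY2 (-0.70) in the authors' deposited table. General stress genes rose, 5 of 36 with 18 adjusted over the list alone (median 0.19, adjusted p = 4.00e-23; adjusted p = 0.0805 with an estimated correlation). For the ribosomal DNA rows the median was -0.70.

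With 55 repeats at 0% glucose, 9 genes rose and 15 fell, and 12 calls remained without the ribosomal DNA rows. RRN11, a core factor of RNA polymerase I, rose by 1.04 (adjusted p = 1.50e-14), the carnitine acetyltransferase CAT2 by 1.01 (3.89e-25) and VPS71 by 0.95 (6.65e-13), and RDN18-2 fell by 1.54, RDN18-1 by 1.53 and COS10 by 1.40 (4.80e-19) in the authors' deposited table. RRN11, CAT2 and VPS71 are neighbours on the chromosome and were also higher at 4% glucose, by 0.94, 0.83 and 0.98 in the authors' deposited table. General stress genes rose as a list, 2 of 36 being called and 18 up and 2 down adjusted over the list alone (median 0.07, adjusted p = 7.84e-20; adjusted p = 0.109 with an estimated correlation). The RNA quality list fell beside it, 6 of 22 with 8 adjusted over the list alone (median -0.34, adjusted p = 5.98e-40; adjusted p = 0.000435 with an estimated correlation), and ribosomal DNA rows had a median of -1.10. Fold changes and p pull apart for some genes of this comparison: HSP12 had 0.10 at an adjusted p of 0.000472, and PCK1 had -0.46 at an adjusted p of 1.00, in the authors' deposited table.

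**Figure D3:**
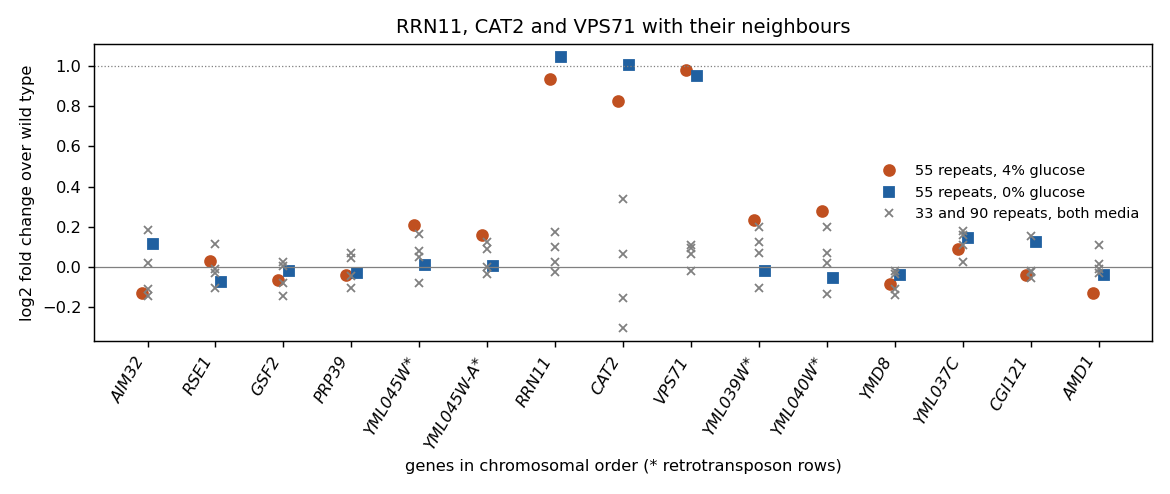
Log2 fold change over wild type (y axis) of RRN11, CAT2 and VPS71 and of the rows on both sides in chromosomal order (x axis) with 55 repeats at 4% glucose (circles) and 0% glucose (squares), and with 33 and 90 repeats in both media (crosses), with retrotransposon rows marked by an asterisk, the media shifted sideways and a dotted line at a 2-fold rise. The 3 genes lie between 0.83 and 1.04 with 55 repeats, and no plotted flanking gene that is not a retrotransposon exceeds 0.15 there.

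With 90 repeats at 0% glucose, the changes were small: FMP16 rose by 0.74 (adjusted p = 9.99e-10), YEL073C by 0.73 (0.00544) and COS12 by 0.72 (2.67e-06) in the authors' deposited table. COS8 fell by 0.57 (adjusted p = 2.27e-05), YCL020W by 0.55 and RDN18-2 by 0.48 in the authors' deposited table. Of 334 called genes, 215 rose and 119 fell, and 4 differed by at least 2-fold. For general stress genes, 26 of 36 rose with 33 adjusted over the list alone (median 0.35, adjusted p = 3.08e-43; adjusted p = 0.00238 with an estimated correlation), among them SOL4 (0.57), CYC7 (0.55), DDR2 (0.54) and HSP12 (0.50) in the authors' deposited table. Ribosome biogenesis genes fell, 17 of 87 with 30 adjusted over the list alone (median -0.16, adjusted p = 1.21e-22; adjusted p = 0.419 with an estimated correlation). The median of the ribosomal DNA rows was -0.40.

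With 105 repeats at 0% glucose, the largest rises in the authors' deposited table were those of HSP26 (2.56, adjusted p = 1.43e-86), the membrane heat shock protein HSP30 (2.09), YML131W (2.08), FIT2 (1.87), CUP1-2 (1.81) and CUP1-1 (1.77). YHR054W-A (1.80), YHR052W-A (1.78), RUF5-1 (1.74) and RUF5-2 (1.73), which lie in the CUP1 repeat, complete the 10 in the authors' deposited table. Falls in the authors' deposited table were led by COS12 (-2.39, adjusted p = 2.80e-26), COS10 (-1.57), MUC1 (-1.35), PGU1 (-1.16), RDN18-2 (-1.0), RDN18-1 (-0.99), IZH4 (-0.94), YER135C (-0.90), OLE1, the fatty acid desaturase (-0.88), and YLR154W-F (-0.82). Of 464 called genes, 345 rose and 119 fell.
Heat shock chaperones rose with 105 repeats at 0% glucose, 13 of 24 with 20 adjusted over the list alone (median 0.36, adjusted p = 2.20e-19; adjusted p = 0.0805 with an estimated correlation), as did iron uptake genes, 9 of 23 with 10 adjusted over the list alone (median 0.18, adjusted p = 5.45e-12; adjusted p = 0.15 with an estimated correlation). FIT3 (1.3), the siderophore transporter ARN1 (1.24) and SSA4 (1.33) were among their members in the authors' deposited table. Glycolytic genes rose, 14 of 23 with 18 up and 1 down adjusted over the list alone (median 0.36, adjusted p = 4.27e-11; adjusted p = 0.274 with an estimated correlation). Flocculins fell, 2 of 9 with 5 adjusted over the list alone (median -0.31, adjusted p = 6.73e-07; adjusted p = 0.109 with an estimated correlation), MUC1 and FLO10 (-0.51) in the authors' deposited table. The general stress list passed upward with a median just under 0, 7 of 36 members having risen, with 8 up and 3 down adjusted over the list alone (adjusted p = 0.00175; adjusted p = 0.67 with an estimated correlation). Ribosomal DNA rows had a median of -0.55.

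Over all variants, 82 of 231 list tests at 4% glucose and 113 of 264 at 0% glucose passed the threshold, and 25 and 6 of these did with an estimated correlation. The alpha-specific, DNA damage, meiosis and strain marker lists passed in no comparison of either medium. Genes encoded in mitochondria held no reads.

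**Figure D4:**
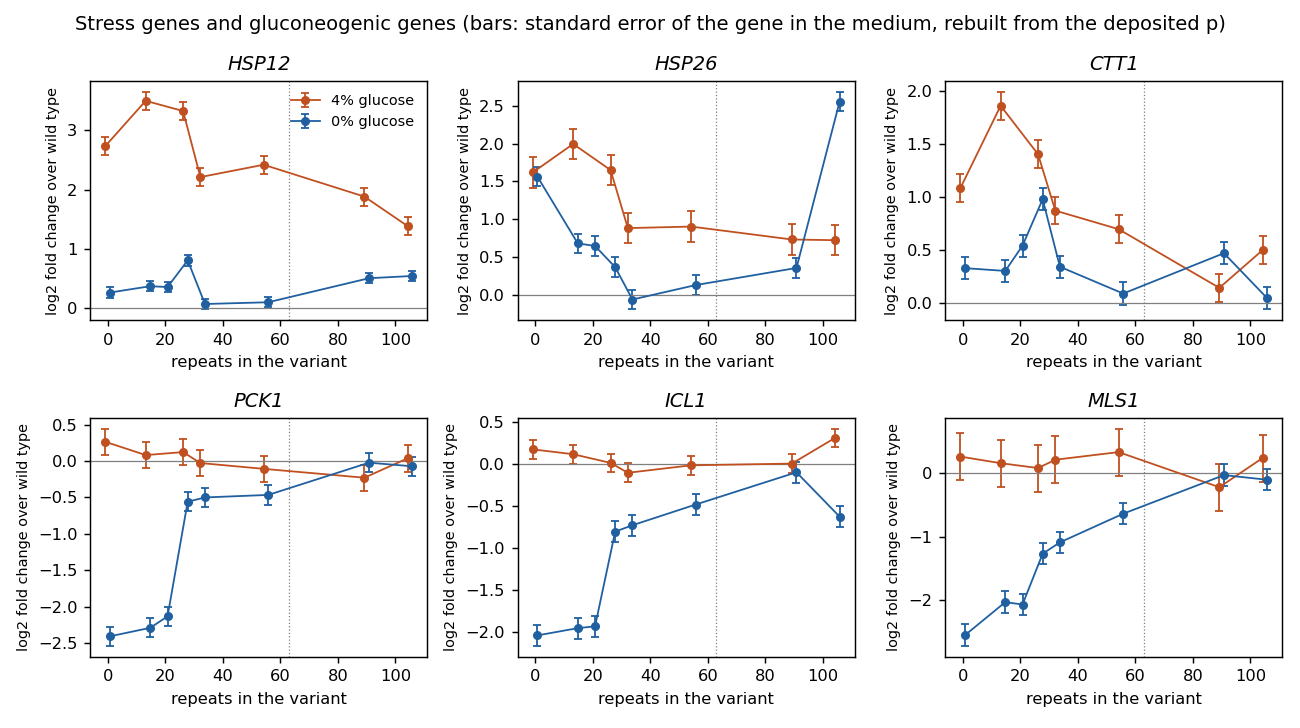
Log2 fold change over wild type of HSP12, HSP26, CTT1, PCK1, ICL1 and MLS1 (y axis) against the number of repeats (x axis) at 4% and 0% glucose, with bars for the standard error of the gene in the medium, rebuilt from the deposited p, wild type's 63 repeats as a dotted line and the media shifted sideways. At 0% glucose PCK1 lies at -2.40, -2.29 and -2.13 with 0, 14 and 20 repeats and HSP26 at 2.56 with 105 repeats.

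Whether expression follows the number of repeats was tested across variants within each medium, with a two-sided exact permutation test for each gene. At 0% glucose 8 of 7006 genes passed after adjustment (adjusted p = 0.0434 for each). ATO2, an ammonium and acetate transporter, YPL277C, YNL024C, FAA4 and ERG26 rose with repeat number (rho of 1), and YAP6, SFG1 and the heme-dependent activator HAP1 fell with it (rho of -1). From 0 to 105 repeats ATO2 went from -0.89 to 0.43 and YAP6 from 0.86 to -0.15 in the authors' deposited table. SKS1 and MIT1 followed with a rho of -0.976 each (exact permutation adjusted p = 0.0567). At 4% glucose 0 of 7009 genes passed after adjustment (lowest exact adjusted p = 0.423). The smallest attainable exact p is 0.000397 with its 7 variants, against 4.96e-05 with the 8 at 0% glucose. The numbers passing therefore do not compare the media, and without the 20 repeat variant 0 genes passed at 0% glucose either. An unadjusted exact p under 0.05 was found for 549 genes at 4% glucose where chance gives 337. The extreme genes at 4% glucose were YNL217W, GAL11 and DED81 (rho of 1), AAP1 and ODC1 (0.964), PDR11 and COX8 (-1), and YNR034W-A, YAP6 and YPR013C (-0.964). At 0% glucose 925 genes had an unadjusted exact p under 0.05 where chance gives 321. Among 100 assignments of repeat numbers to variants, the real one included, 7 gave as many at 0% and 11 at 4% glucose, so chance could not be excluded. Without any single variant of the 8, or without the 90 and 105 repeat variants, 0 genes passed after adjustment; the smallest exact p rises from 4.96e-05 with 8 variants to 0.000397 with 7 and 0.00278 with 6.

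Of 32 lists per medium, none followed repeat number after adjustment with Spearman's rho over the variants. The gluconeogenic list at 0% glucose had a rho of 0.881 (exact permutation p = 0.00724, adjusted p = 0.171) and Pearson's r of 0.816 (exact permutation p = 0.0142, adjusted p = 0.205). With wild type added at 63 repeats it passed (rho 0.917, exact permutation adjusted p = 0.0420). The strain construction markers at 4% glucose passed with Pearson's r (exact permutation adjusted p = 0.0190) and with wild type added (rho 0.976, exact permutation adjusted p = 0.0127). Without the variants farthest from the median repeat number, 90 and 105, the gluconeogenic list had a rho of 0.771 (exact permutation p = 0.103, adjusted p = 0.299) and an r of 0.815 (exact permutation p = 0.0347, unadjusted). Corepressor partners at 0% glucose had a rho of -0.762 (exact permutation p = 0.0368, adjusted p = 0.196) and r of -0.697 (exact permutation p = 0.0513), and without 90 and 105 repeats a rho of -1 (exact permutation adjusted p = 0.0889) and an r of -0.988 (exact permutation p = 0.00139, unadjusted). The general stress list at 4% glucose had a rho of -0.643 (exact permutation p = 0.139) and r of -0.568 (exact permutation p = 0.183), and without those 2 variants a rho of -0.6 (exact permutation adjusted p = 0.589) and an r of -0.507 (exact permutation p = 0.375, unadjusted).

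Whether a variant's effect differs between the media was tested gene by gene, as 4% minus 0% glucose, with the rebuilt standard errors. With 0 repeats, 167 genes differed, 100 of them higher at 4% glucose. PCK1 had 0.26 and -2.40 at 4% and 0% glucose, ICL1 0.17 and -2.04, IDP2 0.33 and -1.60, HSP12 2.74 and 0.26, and DDR2 2.03 and -0.25 in the authors' deposited table. The differences were 2.67 for PCK1 (SE 0.224) and 2.48 for HSP12 (SE 0.175), with adjusted p of 2.53e-29 and 9.88e-42. In the other direction, CLB6 had -0.28 and 1.16 and IMA1 0.21 and 1.35 in the authors' deposited table, beside the ribosomal DNA rows YLR154W-F, RDN18-1 and RDN18-2.
With 14 repeats 201 genes differed between media, 140 of them higher at 4% glucose: the lactate and pyruvate permease JEN1 had 1.03 and -1.03, HXK1 2.05 and 0.02, and HSP12, PCK1 and ICL1 also led, in the authors' deposited table. FIT2 (-0.88 and 0.30), the cell separation gene DSE4 (-0.27 and 0.78), YGR035C (-0.21 and 0.66), CLB6 and IMA1 led the other direction in the authors' deposited table. With 27, 33, 55 and 90 repeats, 44, 34, 2 and 13 genes differed, or 27, 9, 10 and 28 with the standard error from the comparison's own p. HSP12 was higher at 4% glucose in each of these variants, by 2.52, 2.14, 2.32 and 1.38 (SE 0.175 each). With 33 and 55 repeats this rests on fold changes at 0% glucose that are out of step with their own p. HXK1, HSP26 and HSP42 were also higher at 4% glucose with 27 and 33 repeats, GRE1 with 27, JEN1 with 33 and HSP42 with 55 repeats. Lower at 4% glucose were 17 genes with 27 and 11 with 90 repeats, the leading 5 of each being ribosomal DNA rows such as RDN18-1 and YLR154W-F, and IMA1 and FIT2 with 33 repeats. With 105 repeats 79 genes differed, 32 higher at 4% glucose: YMR316C-B (1.87 and -0.40), YMR317W (1.63 and 0.00), YDL023C (0.87 and -0.25), ADR1 (1.05 and 0.05) and FLO10 (0.48 and -0.51) led in the authors' deposited table. The other direction was led by HSP30 (0.01 and 2.09), HSP26 (0.72 and 2.56), YMR018W (-0.16 and 1.65), CUP1-2 (0.40 and 1.81) and YHR054W-A (0.39 and 1.80), in the authors' deposited table. The gluconeogenic list differed with 0 repeats, 14 members being higher at 4% glucose and none lower (median difference 0.75, adjusted p = 8.63e-66; adjusted p = 0.00117 with an estimated correlation), and with 14 repeats, where 12 were higher (median difference 0.67, adjusted p = 1.49e-40; adjusted p = 0.0421 with an estimated correlation). No other list did so with an estimated correlation in any of the 7 variants. The general stress list with 14 repeats lay just above the threshold. There 17 members were higher at 4% glucose and 0 lower (median difference 0.54, limma adjusted p = 1.86e-40, or 0.0522 with an estimated correlation). Beside these, the RNA quality list was lower at 4% glucose with 0 repeats, in 6 members with 0 higher (median difference -0.50, adjusted p = 1.18e-08; adjusted p = 0.674 with an estimated correlation). With 14 repeats 0 of its members differed (median difference -0.15, adjusted p = 0.984; adjusted p = 0.994 with an estimated correlation). With 27 repeats 6 of its members were lower at 4% glucose and 0 higher (median difference -0.59, limma adjusted p = 2.99e-26, or 0.0522 with an estimated correlation). The estimated correlation was added to the difference tests after the data were seen.

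The longest variant was set directly against the shortest, as 105 minus 0 repeats, with standard errors from each comparison's own p. At 4% glucose 200 genes differed, 128 higher with 105 repeats: HBN1, YLL053C, YRO2, the aquaporin AQY2 and YMR317W were higher by 2.37 (SE 0.222), 2.33 (SE 0.205), 2.26 (SE 0.185), 2.21 (SE 0.214) and 1.53 (SE 0.221). YER135C, TIR3, HSP12, PGU1 and MUC1 were lower, with differences of -1.44 (SE 0.147), -1.42 (SE 0.152), -1.35 (SE 0.147), -1.22 (SE 0.158) and -1.20 (SE 0.113). The a-specific list was lower with 105 repeats, 5 of its 7 members being called (median difference -0.72, adjusted p = 1.83e-15; adjusted p = 0.000793 with an estimated correlation). The RNA quality list was higher with 105 repeats at 4% glucose, 8 members being called and 0 lower (median difference 0.78, adjusted p = 6.01e-16; adjusted p = 0.110 with an estimated correlation). At 0% glucose 0 of its members were called (median difference -0.07, adjusted p = 0.204; adjusted p = 0.881 with an estimated correlation). At 0% glucose 646 genes differed, 390 higher with 105 repeats, among them ALP1 (1.22 against -1.36), YML131W (2.08 against -0.43), MLS1 (-0.10 against -2.56), ADY2 (0.04 against -2.31) and PCK1 (-0.07 against -2.40) in the authors' deposited table. MUC1 (-1.35 against 0.57), COS12 (-2.39 against -0.79), TIR3 (-0.23 against 1.36), YER135C (-0.90 against 0.52) and COS10 (-1.57 against -0.23) were lower in the authors' deposited table. The gluconeogenic list was higher with 105 repeats at 0% glucose, in 22 of 27 members (median difference 0.78, adjusted p = 6.86e-60; adjusted p = 0.000793 with an estimated correlation). The share of the variance owed to wild type was assumed, and with none taken off 80 genes differed at 4% glucose and 238 at 0% glucose.

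Calls shared between variants were counted over all pairs of a medium. Only genes with a mean log2 CPM of at least 2 and outside the ribosomal DNA locus were counted (5994 at 4% and 6124 at 0% glucose). Of the ribosomal DNA rows left out, 15, 12, 12, 12, 12 and 10 fell with 0, 27, 33, 55, 90 and 105 repeats at 4% glucose. With 14 repeats 0 fell and 3 rose, and 3 rose with 105 repeats. The shared falls below leave these rows out. Summed over 21 pairs at 4% glucose, 418 rises were shared where independent calls give 13.3, and 21 falls where they give 0.178. Over 28 pairs at 0% glucose, 1176 rises were shared against 189 and 611 falls against 80.4. With 0 and 14 repeats at 0% glucose, 217 genes rose in both and 127 fell in both, against 31.3 and 16.7, and 14 and 20 repeats shared 142 rises and 159 falls. Across genes, which are not independent replicates, log2 fold changes of 2 variants correlated between 0.142 and 0.815 at 4% glucose. At 0% glucose the range was -0.0758 (33 and 105 repeats) to 0.899 (14 and 20 repeats). Simulated unchanged groups against shared wild type libraries gave about 0.499. That value follows from the equal variances assumed for variant and wild type, and the simulated covariance rests on the same assumption. The covariance lay above the simulated one in 11 of 21 pairs at 4% glucose and in 20 of 28 pairs at 0% glucose. All comparisons of a medium use the same 2 wild type libraries, so these libraries contribute to the sharing by an amount the tables cannot give.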

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

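All tests weighed in this part against technical explanations were chosen after the result was seen, and so was the estimated correlation for the difference tests.

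What drew attention was that the effect of a variant differed between 4% and 0% glucose by a test of the difference itself. The number of genes whose effect differed was 167 with 0 repeats, 201 with 14, 44 with 27, 34 with 33, 2 with 55, 13 with 90 and 79 with 105 repeats. The number of gene lists was 18, 14, 12, 11, 10, 12 and 15 in the same order. With an estimated correlation 1 list was kept with 0 and 1 with 14 repeats, the gluconeogenic list in both, and 0 in each of the others. With the standard error from the comparison's own p, the numbers of genes were 157, 218, 27, 9, 10, 28 and 97 in the same order. The 2 genes with 55 repeats were HSP12 and HSP42. HSP12 is among the genes whose fold change and p pull apart at 0% glucose with 33 and 55 repeats, so its differences there are in doubt.

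The gluconeogenic and glyoxylate cycle genes were lower with 0, 14 and 20 repeats at 0% glucose. A weaker overall response to glucose removal would lower all induced genes in step. The slope against the wild type response was taken across responding genes outside the list, induced and repressed together. It was 0.002 of the slope over the list with 14 repeats and -0.117 with 20. The 95% bootstrap intervals were -0.057 to 0.070 and -0.220 to -0.051, genes treated as independent. This argues against a shift of all responding genes in step for these 2 variants. Induced genes were not fitted alone. With 0 repeats the ratio was 0.307 (interval 0.228 to 0.428). Other responding genes were shifted the same way there, though less, so a partly weaker response cannot be excluded with 0 repeats. Wild type levels at 0% glucose enter both the fold changes and the response, which limits the test. Carry-over of ribosomal RNA would shift the ribosomal DNA rows alike, but their median reached 1.08 with 20 repeats and was -0.54 with 0 repeats, which argues against it as well. High gluconeogenic transcripts in the 2 shared wild type libraries would lower the list in each variant alike. They drop out when 90 or 105 repeats are set against 0, 14 or 20, where at least 12 of 27 members were higher and 0 lower (105 against 20 repeats), which argues against them as the cause. Strain differences outside SSN6 were not tested, so a link between short repeats and these genes is a hypothesis.

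General stress genes were higher at 4% glucose with 0, 14, 27, 33 and 55 repeats. With 90 and 105 repeats the list did not pass with an estimated correlation (adjusted p = 0.390 and 0.271). Low stress transcripts in the 2 shared wild type libraries could raise the list in each variant alike. They drop out when 14 repeats are set against 90 repeats, where 8 list members were higher and 0 lower (CTT1, CYC7, GPH1, GSY1, HSP12, HSP26, PNC1 and TSL1), which argues against that explanation for the part that differs between variants. A sign of RNA quality differed between these 2 variants as well. The ribosomal DNA rows had a median of -0.31 with 14 and -1.27 with 90 repeats. With 14 repeats 3 of these rows were called and rose, and with 90 repeats 12 were called and fell. The RNA quality list was called with 90 repeats (limma adjusted p = 1.39e-56) and not with 14 (limma adjusted p = 0.681). That list holds rows of the same locus, so it is not a separate sign. Whether this difference in RNA quality adds to that in stress genes was not tested. The median of those rows lay below 0 in each of the 7 variants at 4% glucose, from -1.44 with 0 to -0.31 with 14 repeats. A high level in the shared wild type libraries and falls in the variants cannot be told apart there. For the part common to all variants, whose lowest list median was 0.086 with 90 repeats, a low wild type and a rise in the variants cannot be told apart, since the tables hold no other reference. An earlier loss of glucose in the cultures would raise other induced genes too. Over other responding genes, induced and repressed together, the slope was at most 0.268 of that over the list with 0, 14 and 27 repeats. Induced genes were not fitted alone here either. The 95% bootstrap intervals of the ratio started at 0.186, 0.173 and 0.103, so other responding genes shifted the same way, though less. This argues against a shift of all responding genes in step, but cannot exclude a partial loss of glucose. Wild type levels at 4% glucose enter both the fold changes and the response, which limits the test. With 33 and 90 repeats the ratio was -0.066 and 0.028, with 95% bootstrap intervals ending at -0.001 and 0.119. There too this argues against a shift of all responding genes in step, but cannot exclude a partial loss of glucose. With 55 repeats the ratio was 0.222 (interval 0.144 to 0.377), and a partial loss cannot be excluded. With 105 repeats the ratio was 0.540 (interval 0.374 to 0.886) and an earlier loss of glucose stays open.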

How the results depend on the processing

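The alternatives without the ribosomal DNA locus and without the 90 and 105 repeat variants, and the tests based on them, were added after the data were seen. 1 result reversed its direction: with ranked log2 fold changes, the general stress list with 105 repeats at 0% glucose went from up to down and no longer passed (adjusted p = 0.937). Of the values that answer a comparison, 138 stayed within 1.5 times of the reported count or, for CYC8 and TUP1, kept direction where called, and 52 moved; 37 of the 138 come from centring. Of the adjusted p of named genes, CYC8 and TUP1 included, all 174 stayed on their side of the threshold at log2 CPM of at least 2. The named rises and falls had been chosen at that level and threshold, so for them this could hardly come out otherwise. At the stricter 0.01, 171 stayed on their side and 3 did not: RDN18-1 with 105 repeats at 4% glucose (0.0251) and CYC8 with 33 (0.0187) and 90 repeats (0.0229) at 0% glucose in the authors' deposited table. Of the tests of called lists, 377 passed again in the same direction and 207 no longer passed, 164 of these with an estimated correlation, 39 with ranked log2 fold changes and 4 at log2 CPM of at least 2. The trends of lists taken here had an unadjusted exact p under 0.05, and none had passed after adjustment. In 33 tests they again did not pass, and in 3 they newly passed. Each of the 2 settings that leave out 2 variants holds 9 of the 33. There even a rho of -1 gave an exact permutation adjusted p of 0.0889 (corepressor partners at 0% glucose), so these tests could hardly pass. Centring moves a whole table by at most 0.02, too little to test the direction of named genes or the percentage that rose. With at least 2-fold required, the called genes at 4% glucose were 27, 36, 32, 18 and 16 with 0, 14, 27, 33 and 55 repeats and 39 with 105; at 0% glucose they were 46, 45, 38 and 15 with 0, 14, 20 and 27 repeats, 4 with 33, 4 with 90 and 64 with 105. Calls shared between variants were then 58 and 4 (rose, fell) at 4% glucose and 32 and 67 at 0% glucose. With an adjusted p under 0.01, the called genes at 0% glucose were 258, 905, 179 and 58 with 0, 14, 20 and 27 repeats and 178 with 90. Without the ribosomal DNA locus, 6 were called with 90 repeats at 4% glucose and 12 with 55 repeats at 0% glucose. With an estimated correlation, 25 list tests passed at 4% glucose and 6 at 0% glucose. Genes with a trend at an exact p under 0.05 numbered 205 at 4% and 472 at 0% glucose without the 0 and 105 repeat variants, and 146 and 458 without 90 and 105, where fewer variants leave fewer attainable p. Leaving out 1 variant at a time gave 286 (without 90 repeats) to 447 (without 33 repeats) genes at 4% glucose. Genes with a trend after adjustment at 0% glucose numbered 80 with Pearson's r, 184 with wild type added, 0 without 0 and 105, 0 without 90 and 105, and 0 without any single variant, by exact permutation. Genes differing between media numbered 27, 9, 10 and 28 with 27, 33, 55 and 90 repeats with the standard error from the comparison's own p, and 8 with 33 repeats at log2 CPM of at least 2. Genes differing between 105 and 0 repeats numbered 80 at 4% and 238 at 0% glucose with no shared variance taken off. Except where the construction of the alternative shows it, the cause was not tested. No paired analysis was possible because the deposit holds no values per library; for that reason leaving out a replicate, other normalizations of counts and other filters on counts were planned but not run. Depth per library and the spread between replicates are unknown, which limits what small changes can show.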

Other observations

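The counts of reassigned repeat numbers were planned; the remaining tests in this part, and the limits used for them, were chosen after the values were seen.

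RRN11, CAT2 and VPS71 lie side by side with retrotransposon rows on both sides, and were higher with 55 repeats in both media. A candidate explanation is a gain of 1 copy of the segment in this strain, independent of SSN6. The median log2 fold change of the 3 genes over both media was 0.966, near that of a doubling, while the 3 nearest genes on each side had medians of -0.04 and 0.02. A graded response to repeat number predicts a shift with 33 and 90 repeats too; there the median furthest from 0 was 0.098, which argues against it. No DNA data were available to test a copy gain directly.

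Chance could not be excluded for the number of genes that follow repeat number. At 4% glucose 549 genes had an unadjusted exact p under 0.05, and 11 of 100 reassignments of repeat numbers to variants, the real one included, gave as many, the highest other giving 712. At 0% glucose the number was 925, reached by 7 of 100, and the highest other gave 1547.

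Some subtelomeric genes differed strongly between strains. As a list they were lower with more repeats, without passing after adjustment: rho was -0.857 at 4% glucose (exact permutation p = 0.0238, adjusted p = 0.364) and -0.786 at 0% glucose (exact permutation p = 0.0279, adjusted p = 0.196). In the authors' deposited table at 4% glucose, COS12 had -0.98 with 0 repeats, 0.67 with 14, 1.04 with 90 and -2.32 with 105. COS12 had the same signs at 0% glucose, with -0.79, 0.98, 0.72 and -2.39 in the authors' deposited table. COS10 fell in the authors' deposited table with 33, 55 and 105 repeats in both media. The list of strain construction markers had the strongest trend among lists at 4% glucose (rho 0.964, exact permutation p = 0.00278, adjusted p = 0.0889; r 0.876, exact permutation p = 0.000595, adjusted p = 0.0190), with no comparison called. Without 90 and 105 repeats its rho was 0.9 (exact permutation adjusted p = 0.427) and its r 0.910 (exact permutation p = 0.05, unadjusted).

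With 55 repeats at 0% glucose, fold changes and p pull apart in the authors' deposited table. Among 3263 genes with log2 CPM over 6, 4 had a log2 fold change beyond 0.35 in size at an unadjusted p over 0.3, and all 4 belong to the gluconeogenic list: ICL1 (-0.48, p = 0.75), ADY2 (-0.48, p = 0.895), PCK1 (-0.46, p = 0.832) and YAT2 (-0.39, p = 0.514) in the authors' deposited table. The other 7 tables at 0% glucose held 0 such genes. In the opposite sense, 20 genes lay under 0.15 in size at an unadjusted p under 0.01, 11 of them general stress genes, against 0 to 4 in the other tables at 0% glucose. This comparison has the highest depth, 136 M reads over its 4 libraries, and no values per library to look into it.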
